A study of Arabidopsis thaliana with 12 samples.

How the data were processed

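Total RNA of 6 WT and 6 psbs samples had been hybridized to an array of 3439 features. The values deposited by the authors are linear intensities, 1 per feature and sample, from 0 to 100, with exact 0 values and no negative ones. Scanner, background correction, scaling and the meaning of the 0 values are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. Gene names came from the platform annotation supplied with the table, matched to the TAIR10.1 gene list for names only: 690 of the 692 features with a single gene matched a locus and 2 did not. No gene was named from a feature with several genes. No genome build was named, so no coordinates are given.

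Column medians differed by more than 1.2-fold, so by a rule set before the data were examined the 12 columns were quantile normalized. Values under the 5th percentile of the pooled positive scaled values (0.0559) were raised to it, and log2 was taken. Differences are on this floored scale, which understates changes of dim features. Scaled values keep rank order within a sample but make the groups' distributions alike, so where most features truly shift 1 way the directions of many calls would change. For that reason further results are given wherever they turn the direction of a gene named by the rule below. These are the results without scaling, with median centring and with cyclic loess. For features above the floor, median centring raises every psbs minus WT difference as deposited by the same amount. A feature higher as deposited is then also higher after median centring, so these are not separate evidence on direction.

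limma 3.58.1 in R 4.3.3 (lmFit and eBayes) compared psbs with WT over all 12 samples, with Benjamini-Hochberg adjustment over the 3359 features tested and a threshold of 0.05. Gene lists with 3 or more measured members were tested with camera (inter-gene correlation preset to 0.01, or estimated) and fry; with 0 values missing or a random block, camera was run on the moderated statistics of the fit. Adjusted p-values of lists cover the 2 lists that could be tested. Single values per sample were compared with two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

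The design, the 17 gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule names PSBS, the 8 largest log2 changes in each direction among called features of a single gene, and for each list the called member with the smallest p in each direction, with the next smallest where 5 or more members were called in that direction, or the member with the smallest p where none was called. Members of these lists outside this rule (PSB27, SBPASE and NTRC) were named after their values were seen, to complete short lists. AT1G64510, also outside it, was named then as an example of a dim member. PSBS was not on a named feature.

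Several choices were made after the data were examined. Exact 0 values were kept at 0 through scaling, because averaging of ties would have put them at different levels in the groups. The 80 features at 0 in all 12 samples were not tested. A further 4 gene lists, the count of calls shared by 4 scalings, and the alternatives without features numbered in multiples of 6, with only features above 0 in all samples and without psbs replicates 1 and 2 were also added then.

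The alternatives set beforehand changed the scaling, the floor (10th percentile, or 0 values missing), the filter on dim features, the replicate number as a block, the handling of consecutive replicate numbers, the sample weights, the variance prior and the samples left out. The procedure was tested on simulated data in which both groups took the WT means and the spread within groups, with independent noise. Among the 3332 features above the floor in that step, it recovered 52 of 100 changed 2-fold and 62 of 99 changed 4-fold. Of its calls 5% were unchanged features. Changes were set equally up and down, and the group-wide shift and the correlation of consecutive numbers were left out. The 5% is therefore not an estimate of false calls in these data.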

Results

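Hybridization signals of total RNA were recorded for 12 samples of Arabidopsis thaliana, 6 from wild type (WT) and 6 from the psbs mutant, both of the Columbia ecotype. The mutant lacks PSII-S, the PsbS protein, which in leaves is needed for the rapid dissipation of excess absorbed light as heat. The comparison asks which transcripts differ in level when this protein is missing. Tissue, age and light regime are not given in the labels. The labels also do not say whether replicates were separate plants, so the p-values measure only the spread between these samples, which may be technical. Samples with consecutive numbers deviated together from their group mean in WT, with correlations across features of 0.459, 0.274 and 0.430. In psbs they were 0.385, 0.0682 and 0.0749, and samples of different pairs reached 0.0462. Pairing was therefore clear in WT but not in psbs replicates 3 to 6. If such pairs are repeats of a single source, each group holds 3 independent values, and an exact permutation test could then not go below p = 0.1.

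The table held 3439 features, of which 3359 were above 0 in at least 1 sample and were tested. A single gene was named for 692 features, several genes for 870 and none for 1877. PSBS itself was named on 0 features, so the loss of its transcript could not be used to check the sample labels. Of the 293 genes in the lists fixed for this comparison, 17 lay on a feature of a single gene. The accounts of gene groups below therefore rest on few members.

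The groups differed in the whole distribution of signal. The median intensity was 0.339 ± 0.0334 (SD, n = 6) in WT and 0.0317 ± 0.00613 (SD, n = 6) in psbs, a ratio of 10.7 (exact permutation test, two-sided, p = 0.00216, the smallest 12 independent samples can give). The share of features at exactly 0 was 13.5% ± 0.320 (SD, n = 6) in WT and 29.8% ± 3.40 (SD, n = 6) in psbs (exact permutation p = 0.00216). The 99th percentile was instead lower in WT, at 10.7, than in psbs, at 16.3. The scale ends at 100, and 6 features were at this top in all 6 psbs samples, against 0 in all 6 WT samples. The number of samples limits the precision of every value.

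PRK, PSAN and PSBY, 3 of the 7 tested genes of the light-harvesting, photosystem and Calvin cycle lists, were higher in psbs under all 4 scalings tried. PRK, which encodes phosphoribulokinase of the Calvin cycle, rose from 1.59 ± 0.138 (SD, n = 6) in WT to 13.0 ± 3.64 (SD, n = 6) in psbs, an 8.18-fold difference in deposited intensity. PSAN, a subunit of photosystem I, rose from 4.33 ± 0.699 to 23.8 ± 8.91 (SD, n = 6 each). PSBY, a small photosystem II protein, rose from 2.15 ± 0.382 to 8.47 ± 2.04 (SD, n = 6 each). For these genes all psbs samples lay above all WT samples, although the log2 difference ranged from 2.098 to 6.38 for PRK, from 1.25 to 5.79 for PSAN and from 1.08 to 5.35 for PSBY across the scalings. Median centring gave the upper end of each range. It raises all differences above the floor alike, so it adds no separate support for a rise to the values as deposited.

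After quantile scaling the log2 difference, psbs minus WT, was 3.19 ± 0.15 (SE) for PRK, with a limma adjusted p of 3.05e-09. It was 2.24 ± 0.25 (SE) for PSAN, with an adjusted p of 7.38e-06, and 1.99 ± 0.14 (SE) for PSBY, with an adjusted p of 1.28e-07. These p-values take the 12 samples as independent. With consecutive numbers averaged the limma adjusted p was 0.000274 for PRK, 0.00414 for PSAN and 0.000926 for PSBY. psbs replicates 1 and 2 held the highest values of each of these genes, and without them the log2 differences were 2.94 for PRK, 1.78 for PSAN and 1.80 for PSBY, all still called.

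**Figure D1:**
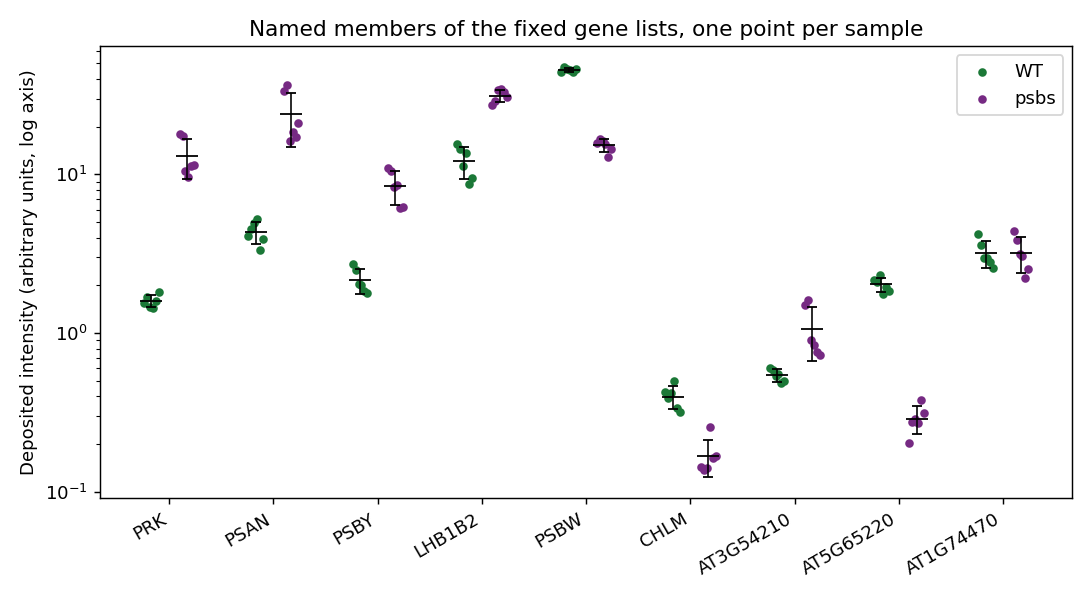
Deposited intensity (arbitrary units, log axis) of 9 named members of the fixed gene lists in each WT sample (green) and psbs sample (purple), with group mean and SD as black bars (n = 6 each). PRK, PSAN, PSBY, LHB1B2 and AT3G54210 lie higher in every psbs sample, while PSBW, CHLM and AT5G65220 lie lower; after median centring PSBW and AT5G65220 turn higher, after any of the other scalings CHLM turns higher, and after loess LHB1B2 is at -0.01.

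Other photosynthetic genes depended on the scaling. LHB1B2, a light-harvesting chlorophyll a/b protein of photosystem II, was at 12.2 ± 2.78 in WT and 31.3 ± 2.90 in psbs (SD, n = 6 each). It rose by 0.65 on the log2 scale (limma adjusted p = 0.00089), but was at -0.01 after cyclic loess. PSBW, a photosystem II subunit, fell by 1.90 on the log2 scale, from 45.4 ± 1.33 to 15.2 ± 1.43 (SD, n = 6 each; limma adjusted p = 1.85e-09), and was higher in psbs, at 1.81, when each sample was centred on its median. PSB27 was at 1.70 ± 0.844 in WT and 2.57 ± 1.21 in psbs (SD, n = 6 each) and did not pass the test (limma adjusted p = 0.0581), but was called higher, at 4.05, after median centring.

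Of the 3 measured photosystem II genes 1 rose, 1 fell and 1 did not pass; adjusted over the list alone, 2 rose and 1 fell, and after median centring all 3 were called higher. Their median log2 difference was 1.18, and the list was not shifted against other features (camera adjusted p = 0.858, and adjusted p = 0.861 with an estimated correlation). The median was 0.65 as deposited and 0.27 after loess. Among the alternatives run with camera the list passed only when samples were centred on their medians, with a median of 4.05 (camera adjusted p = 0.0223). The fry test, which asks whether members move one way on balance without setting them against other genes, gave an adjusted p of 0.000263. Its direction was not recorded, and it weighs each member against its spread. PSBW, which fell by 1.90, had the smallest SE, 0.08, against 0.14 for PSBY and 0.49 for PSB27. The fry value is therefore no support for a rise of the list. In the Calvin cycle list PRK rose and SBPASE did not pass (limma adjusted p = 0.0755). SBPASE was listed at 0 in all 6 WT samples and in 3 psbs samples, with a psbs mean of only 0.00453. Its difference as deposited was 0.0084 (limma adjusted p = 0.916). Adjusted over the list alone 2 rose, but SBPASE was called lower, at -0.44, after loess.

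Genes for plastid ribosomal proteins moved in both directions. Of 6 measured members, 2 rose, 1 fell and 3 did not pass, and 3 rose and 1 fell adjusted over the list alone. As deposited 1 was called higher and 3 lower, and after median centring 3 higher and 0 lower. AT3G54210, for ribosomal protein L17, rose from 0.545 ± 0.0488 to 1.06 ± 0.398 (SD, n = 6 each) and was higher under all 4 scalings. AT5G65220, for L29, fell from 2.03 ± 0.207 to 0.289 ± 0.0581 (SD, n = 6 each), but was higher, at 0.57, after median centring. The list median was 0.57 (camera adjusted p = 0.622, and adjusted p = 0.647 with an estimated correlation) and -0.96 on the values as deposited. It depended on its dimmest members, among them AT1G64510, listed at 0 in all 6 WT samples on a feature numbered by a multiple of 6, and was 0.11 after loess and 1.72 without the dimmest features; the list passed camera under none of the alternatives run. The fry adjusted p was 3.32e-06, with no direction recorded.

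The remaining lists with a measured gene had 1 or 2 tested members. AT3G52960, for the plastid peroxiredoxin IIE, fell: it was at 0.270 ± 0.00896 (SD, n = 6) in WT and was listed at 0 in 5 psbs samples. NTRC, the other antioxidant gene measured, did not pass (limma adjusted p = 0.479), but was called lower as deposited, at -2.58 (adjusted p = 0.00179). CHLM, for the magnesium protoporphyrin IX methyltransferase of chlorophyll synthesis, had the lower deposited intensity in psbs, 0.169 ± 0.0451 against 0.399 ± 0.0670 (SD, n = 6 each). It was called higher after quantile scaling (limma adjusted p = 1.23e-05), and called lower on the values as deposited, with a log2 difference of -1.26. AT1G74470, for geranylgeranyl reductase, was at 3.19 ± 0.610 in WT and 3.20 ± 0.801 in psbs (SD, n = 6 each) and did not pass (limma adjusted p = 0.732). Its call followed the scaling: it was called higher after median centring, at 3.38 (limma adjusted p = 2.41e-07), and lower after loess, at -0.76 (limma adjusted p = 0.00312). No member of the electron transport, light stress, plastid import, plastid transcription, starch, jasmonate, fatty acid, or seed and root lists was on a tested feature of a single gene.

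Among all features of a single gene, those with the largest increases included further chloroplast proteins. The largest decreases, given below, also included a thylakoid protein, and the share of chloroplast proteins among all features was not examined. AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, rose from 0.180 ± 0.0209 to 0.710 ± 0.0652 (SD, n = 6 each), a log2 difference of 3.62. AT3G47650, the BSD2 chaperone of Rubisco assembly, rose from 0.926 ± 0.170 to 4.28 ± 1.15 (SD, n = 6 each), a log2 difference of 2.84. AT1G51080, AT2G21530, AT4G38490, AT1G04420 and AT3G14890 rose by 3.98, 3.75, 3.40, 3.26 and 2.84 on the log2 scale after quantile scaling, and were higher by 2.38, 2.26, 1.97, 1.26 and 0.67 as deposited. As deposited the difference was 1.98 for AT2G04700, and for AT3G47650 it was smallest after loess, at 1.76. All of these were called higher under each of the 4 scalings, although WT and psbs samples overlapped in deposited intensity for AT1G04420 and AT3G14890.

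The largest decreases included AT1G76450, a PsbP-domain protein of the thylakoid, which fell from 8.19 ± 2.08 to 0.378 ± 0.142 (SD, n = 6 each), a 21.7-fold difference in deposited intensity. AT4G31530 fell from 54.3 ± 8.69 to 2.59 ± 1.35 (SD, n = 6 each), a 20.9-fold difference. AT3G52070, CUTA and AT1G16080 fell by 4.29, 4.02 and 3.96 on the log2 scale after quantile scaling. As deposited their differences were -6.92, -7.03 and -5.99, and after median centring -3.53, -3.99 and -2.71. AT2G46300 was at 1.87 ± 0.239 (SD, n = 6) in WT and was listed at 0 in all 6 psbs samples. These 6 genes were called lower under all 4 scalings, with differences of only -1.12 for AT1G76450 and -1.24 for AT4G31530 after median centring. AT2G27290 fell from 39.6 ± 2.40 to 3.66 ± 1.53 and AT4G17070 from 18.4 ± 4.40 to 2.14 ± 1.06 (SD, n = 6 each); after median centring AT2G27290 was at -0.19 and AT4G17070 at 0.13, and neither was called.

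**Figure D2:**
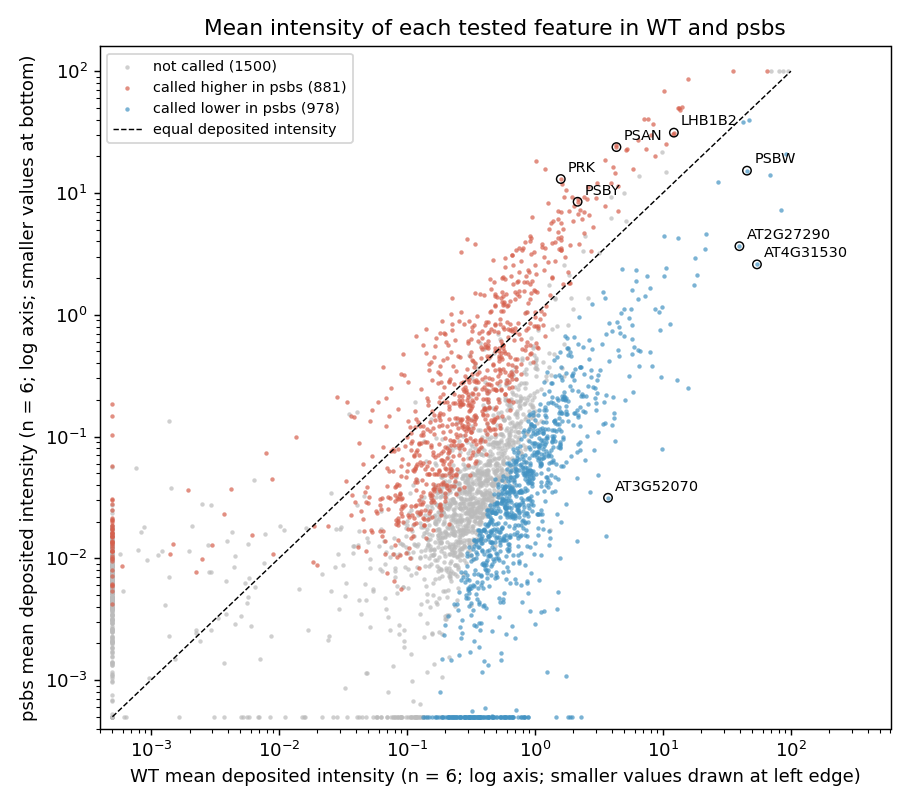
Mean deposited intensity of each tested feature in WT (horizontal, log axis) and psbs (vertical, log axis), n = 6 each, coloured by the limma call after quantile scaling, with the line of equal intensity dashed. Of the called features 881 were higher and 978 lower in psbs, and many of those called higher lie below the dashed line.

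Over all features, limma called 1859 of 3359 (55.3%) at an adjusted p under 0.05, 881 higher and 978 lower in psbs. The share of calls that were higher was 47.4%, a balance largely set by quantile scaling, which makes the distributions of the groups alike. Among features of a single gene 370 were called, 148 higher and 222 lower. The split followed the scaling: 248 higher and 2453 lower as deposited (9.18% higher), and 881 higher and 692 lower after median centring (56.0% higher). The median log2 difference of all features was -2.86 as deposited, 0.05 after quantile scaling, 0.12 after median centring and -0.02 after loess, so each difference is relative to that shift.

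Of the 881 features called higher, 531 had a negative difference as deposited. Under all 4 scalings 220 features were called higher and 468 lower, of which 28 and 105 carried a single gene. The values as deposited gave only 248 higher calls against 2453 lower, which caps the shared higher count. The excess of shared lower calls is therefore no measure of the balance of directions. The 28 also include genes listed at 0 in all WT samples, with mean psbs intensities as low as 0.0152. Without psbs replicates 1 and 2 the counts under all 4 scalings were 269 higher and 635 lower, and 206 and 439 features were shared with the counts over all samples. For 1315 features (39.1%) the scaled values of the groups did not overlap, against 0.216% by chance if the 12 samples are independent. If consecutive numbers are repeats of a single source, chance would give far more, as an exact permutation test could then not go below p = 0.1. The labels give no hybridization batch, so a batch that coincided with the groups and the genotype cannot be told apart.

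Samples within a group were more alike than samples of different groups. Pearson correlations of scaled log2 values across features, which are not independent replicates, ran from 0.961 to 0.987 within WT, from 0.762 to 0.885 within psbs and from 0.575 to 0.627 between the groups. psbs replicates 1 and 2 correlated at 0.881 with each other and at 0.762 to 0.781 with replicates 3 to 6. Leaving out psbs replicates 1 and 2 gave 2022 called features, and 1738 of the 1859 calls kept their direction.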

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

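The test of features at 0 in all psbs samples and the splits of averaged pairs were set before their results were seen; the other tests in this part were chosen or written down only after the results were seen. Whether a sample lay far from the other 5 of its group was examined for 3 measures per sample and for the 25 named genes, these on both deposited intensities and scaled log2 values, because the choice of scale was made after the values were seen and changes which samples stand out. Chance alone picks about 5% of groups, and 104 groups with any spread were examined.

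AT3G52960 in psbs replicate 6 was at an intensity of 0.0187, or -2.89 on the scaled log2 scale, with all other psbs samples at 0. CHLM in psbs replicate 4 was at an intensity of 0.257, against 0.138 to 0.170 in the others. AT1G51080 in WT replicate 4 was at -3.61 on the scaled log2 scale, against -4.16 to -3.97. AT2G27290 in WT replicate 6 was at 5.54 on the scaled log2 scale, against 5.37 in all others, which share a rank; its intensity of 39.6 lay inside their range. AT1G74470 in WT replicate 1 was at 1.96 on the scaled log2 scale, against 1.47 to 1.62.

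The groups differed at 1859 of 3359 features. If the 12 samples are independent, chance can be excluded: only 1 of 100 splits, the real one, gave as many calls, and the highest other split gave 1. The pairing of consecutive numbers in WT goes against that condition, with a limma consensus correlation of 0.473 over both groups. With consecutive numbers averaged the real split gave 1585 calls and the highest other 0, but only 1 of 10 splits can be the real one, too few for a share under 0.05. A monotone difference in exposure, gain or background would keep the rank order of features, yet over the 1407 features above 0 in all samples the median Spearman correlation between WT and psbs was 0.403 (0.381 to 0.440), below the lowest within psbs, 0.695. A difference between hybridization batches and the genotype stay open and cannot be told apart, because 0 labelled batches hold both groups.

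Features whose number is a multiple of 6 were at 0 in all 6 WT samples in 197 of 261 cases (75.5%), against 172 of 3178 (5.41%) for other numbers, and in psbs 60.9% of their values were at 0, against 27.2%. Multiples of 6 were also scarcer in the table, with 261 features against 593 to 658 for each other remainder. The reason for this scarcity was not tested. Among features at 0 in all 6 psbs samples, 28 of 32 multiples of 6 (87.5%) were also at 0 in all WT samples, against 52 of 227 others (22.9%; Fisher's exact test, p = 1.45e-12). This gap had been set to count against low expression at these numbers, but an excess of unexpressed genes there would widen it too, so low expression stays open. The excess in WT was at least 20 percentage points in 11 of 12 blocks of feature numbers, which describes how widely it is spread and does not test its source. Handling of values tied to the feature number stays open as well, since no source used here records such a step, and no biological explanation was tested.

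psbs replicates 1 and 2 stood apart from replicates 3 to 6. Carry-over of WT signal would raise all features bright in WT and at least 10-fold lower in psbs replicates 3 to 6, but 12 of 22 such features were not raised. Deviations of replicates 1 and 2 from the psbs mean correlated at 0.385, but samples that stand apart from the rest of their group deviate together whatever the reason, so this value decides nothing. A shared filter or hybridization and shared plant material stay open, as the labels record neither, and no biological explanation was tested.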

How the results depend on the processing

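The alternatives using only features above 0 in all samples, leaving out multiples of 6 and leaving out psbs replicates 1 and 2 together were chosen after the data were examined. Over all alternatives the number of called features ran from 1077 to 2701. The lowest count came from testing only the 1407 features above 0 in all samples (556 higher, 521 lower, 51.6% higher), where fewer features were tested. For the other values in this part the cause was not tested.

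As deposited, 248 features were higher and 2453 lower (9.18% higher), the plastid ribosome median was -0.96, AT1G74470 was at -0.0094 and CHLM at -1.26. After median centring 56.0% of calls were higher, the photosystem II median was 4.05, AT4G17070 was at 0.13, AT5G65220 at 0.57 and PSBW at 1.81. After cyclic loess AT1G74470 was at -0.76 and LHB1B2 at -0.0088. The share of higher calls was 61.3% with 0 values missing, 44.4% without the dimmest features and 50.9% with sample weights. AT1G74470 was at -0.051 with only features above 0, at -0.10 without psbs replicates 1 and 2 together and at -0.011 without psbs replicate 1. The plastid ribosome median was 0.11 after loess, 0.31 with the floor at the 10th percentile, 0.86 without multiples of 6, 1.48 with only features above 0, 1.71 with 0 values missing and 1.72 without the dimmest features, and the photosystem II median 0.65 as deposited and 0.27 after loess, with no camera call among these. Under fry the plastid ribosome list had an adjusted p of 3.32e-06 and photosystem II 0.000263, with no direction recorded for either.

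Leaving out each sample in turn gave 1734 to 1925 called features, 828 to 938 higher, 906 to 987 lower and 47.4 to 48.7% higher, medians of 0.37 to 0.72 for the plastid ribosome and 0.87 to 1.41 for photosystem II, and 194 to 227 features higher and 378 to 507 lower under all 4 scalings. With the replicate number as a block 1833 features were called, and no call of a named gene or list changed. Same-numbered WT and psbs samples deviated together with correlations of 0.0569 to 0.154, not all over 0.1, so the numbers were not taken to pair the samples, although each sample correlated best with its own number. Averaging consecutive replicate numbers gave 1585 calls, and treating them as a random block 1520. The mean of several features per gene was not run, because no list gene had several. PSBS has no value under any alternative. Signal at or below the 0 level limits what can be measured in psbs, where 29.8% of features were at 0.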

Other observations

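The tests in this part were chosen after the data were examined, and the genes of this paragraph were chosen after their values were seen, from those called in the same direction under all 4 scalings. RAP74, a subunit of the general transcription factor TFIIF, rose from 2.54 ± 0.530 to 8.85 ± 0.938 (SD, n = 6 each). AT5G38360 rose from 13.5 ± 2.28 to 50.2 ± 6.29 (SD, n = 6 each). Across the 4 scalings the smallest log2 difference was 0.91 for RAP74 and only 0.40 for AT5G38360. Among the genes that fell, Z-ISO, the carotenoid pathway's zeta-carotene isomerase, was at 0.649 ± 0.0483 in WT and 0.0223 ± 0.0256 in psbs, and AT-HF, an enzyme of histidine synthesis, at 1.06 ± 0.113 and 0.0157 ± 0.0285 (SD, n = 6 each). CHL, the chloroplast lipocalin, was at 0.207 ± 0.0254 in WT (SD, n = 6) and was listed at 0 in all psbs samples. The smallest absolute log2 difference across the scalings was 1.08 for Z-ISO, 2.36 for AT-HF and 0.69 for CHL.

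A hypothesis was that genes of the photosynthetic apparatus may be higher in psbs relative to other features. The light-harvesting, photosystem, electron transport and Calvin cycle lists, pooled, had 7 tested members, of which 4 were called higher and 1 lower, both after quantile scaling and as deposited, with a median log2 difference of 1.18 after quantile scaling. After median centring 6 were called higher and 0 lower, with a median of 4.78, and after loess 3 higher and 2 lower, with a median of 0.27. The camera test gave p = 0.0509 and, with an estimated correlation, p = 0.0721 (adjusted p = 0.289 over 4 lists), so the data leave this open. The fry adjusted p over 4 lists was 9.56e-07, with no direction recorded. As fry does not set members against other features, it cannot decide this hypothesis. The median lay at the 78.4th percentile of random lists matched on level.

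A further 3 lists were described without a hypothesis. Of 7 genes for thylakoid NDH and complex assembly, 3 were called higher and 1 lower after quantile scaling, but 0 higher and 4 lower as deposited. The counts were 3 and 1 after median centring and 2 and 1 after loess. NdhS, called lower after quantile scaling, at -1.68 (limma adjusted p = 4.79e-07), was called higher after median centring, at 1.70 (limma adjusted p = 2.44e-08). NdhN, 1 of the 3 called higher after quantile scaling (limma adjusted p = 0.0413), was at 0 in 3 WT samples. It lies on a feature numbered by a multiple of 6, most of which are at 0 in WT. NdhN was called under no other scaling, at 0.04 as deposited, 0.66 after median centring and 0.17 after loess. CRR21, OTP70, OTP85, ATAB2 and OSB1 were grouped as organelle RNA genes, and whether each has such a role was not examined. Of these 5 genes, 1 was called higher and 1 lower after quantile scaling, against 0 and 4 as deposited. The counts were 0 and 1 after median centring and 0 and 0 after loess. AGL103, AGL26, AGL54, SPL and DME were likewise grouped as flower regulators, and their roles were not examined either. Of these 5 genes, 1 was called higher and 2 lower after quantile scaling, against 0 and 4 as deposited. The counts were 2 and 2 after median centring and 1 and 1 after loess. The camera adjusted p with an estimated correlation was 0.916 for each of these lists. The fry adjusted p, with no direction recorded, was 0.00443 for thylakoid NDH and assembly, 0.330 for organelle RNA and 0.389 for flower regulators.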
